A study of Mus musculus with 2 samples.

How the data were processed

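The deposited values were raw UMI counts per gene and cell barcode from 10x Genomics 3' libraries (v3.1 chemistry, Chip G, paired reads of 150 bp, per the labels' protocols). The authors made these counts with Cell Ranger 5.0.0, per the file headers. STAR, Seurat 3.2.2 and the mouse build mm10/GRCm38 are named per the submitters' processing notes. The annotation release is not given in the sources used here. The deposited barcodes were those that the authors kept, and the lowest held 502 UMIs in the Dox library and 500 in the vehicle library. Per the labels' protocols, the explants came from adult mice, the vestibular region, middle ear, ligament portion and Reissner's membrane were removed, and the sensory epithelium was dissociated with trypsin. The labels give about 3000 (Dox) and 1100 (vehicle) recovered cells, beside 3005 and 1103 barcodes in the matrices. Each group was 1 library, so no test was made and no p-value is given. A pool of animals or explants gives no measure of the spread between them.

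Barcodes with under 500 genes (330 Dox, 87 vehicle) or over 20% mitochondrial UMIs (106 Dox, 26 vehicle) were removed. Scrublet, as implemented in Scanpy 1.11.5, was run per library at an expected rate of 0.8% per 1000 cells (2.12% and 0.811%) with its automatic threshold. It called 0 Dox and 4 vehicle cells, which were removed, so doublets may remain. This left 2649 Dox cells (88.2%) with 34674590 UMIs and 1010 vehicle cells (91.6%) with 19162693 UMIs, at median mitochondrial shares of 1.51% and 1.17%. Genes in at least 3 cells were kept for clustering. Coordinates came from GENCODE M21 on GRCm38, in which 30934 gene identifiers of the matrix were found. Of genes that share a symbol (36 symbols), the one with the most UMIs kept it.

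Both libraries were clustered together without batch correction, on 2000 variable genes and 30 principal components. A shared-neighbour graph of 10 neighbours (edges under a Jaccard index of 0.05 removed) was divided by the Leiden method at resolution 1.0, which gave 23 clusters. A cluster took the class whose markers scored highest. It stayed unnamed with under 3 detected markers (at least 20 CPM and 0.2 of the highest cluster), with more top genes of another class, or with low depth and no marker among its top 10 genes. It also stayed unnamed if the class was not the commonest own best class of its cells (scores of at least 0.1). Top genes were ranked by fold with 10 CPM added and detection in at least 20% of cells. Supporting cell, other cochlear epithelial and stria marginal markers were merged into an epithelial class, and the mesenchymal lists were merged likewise. In all, 16 clusters were named and 7 were not.

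Several of these clustering choices were made after the data were examined. At resolution 1.0, 6 graphs were looked at: a weighted UMAP graph of 15 neighbours, shared-neighbour graphs of 20, 15 and 10 neighbours, the last also without pruning, and the last split again at resolution 0.5. The graph of 10 neighbours was kept because neurons, hair cells and the Pou4f3 and Ccer2 cluster came apart in it. Of naming rules, 5 were looked at: unmerged lists, merged lists, stria marginal markers merged too, at least 50% of cells with the class as own best, and the commonest own best class. The last replaced the 50% rule after that rule was seen to leave the Pou4f3 and Ccer2 cluster (47.3% of cells) unnamed. The choice was therefore not independent of the hair cell-like share, and both clusters are reported separately. The marker levels and score minimum were set after seeing the data too. The commonest-class rule kept out cluster 4 (8.27% of Dox and 9.70% of vehicle cells), cluster 9 (2.79% and 8.61%) and cluster 11 (1.66% and 8.51%). Of the other unnamed clusters, cluster 0 (12.7% and 4.85%) had more top genes of another class. Clusters 1 (11.4% and 2.48%), 6 (7.81% and 1.78%) and 18 (1.70% and 0.099%) had low depth with no marker among their top genes.

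Gene values were UMI sums per library, or per library and class, scaled to CPM by the total UMIs, with exact Poisson intervals for levels, exact conditional binomial intervals for ratios and exact Clopper-Pearson intervals for shares. The confidence level was 95%, and these intervals cover counting error only. A count of 0 was set to 3 counts in the library concerned, which gives a bound. No direction was read where an alternative left at most 3 counts in both libraries, or 0 in a library with an interval that included 1. Classes with at least 50 cells in both libraries were compared, and the hair cell-like class with at least 20. In these scopes 11573 (whole libraries), 11708 (epithelial-like), 7343 (hair cell-like), 9211 (mesenchymal-like) and 5858 (glial cell-like) genes were eligible for naming.

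The rule for named genes was set before the data were examined, as were the gene and marker lists. It took the 12 highest and 12 lowest genes by the interval bound nearest to 1, among genes with at least 100 UMIs (50 within a class) and a UMI in at least 5% of cells of a library. Unnamed gene models and ribosomal, mitochondrial, haemoglobin, immunoglobulin and sex-linked genes were left out. A gene that the rule named in glial cell-like cells is not reported here. Members of 23 gene lists and 19 marker lists (223 markers) were counted as at least 1.5-fold higher, at least 1.5-fold lower or in between if they had at least 10 UMIs. The gene lists were engineered genes, Notch targets, Notch ligands, Myc targets, S phase, G2 and M phase, cell cycle inhibitors, nascent and mature hair cell genes, otic progenitor genes, Wnt targets and supporting cell function. They also covered extracellular matrix, interferon response, MHC class I, inflammatory genes, immediate early genes, p53 and stress response, glycolysis, cholesterol synthesis, metallothioneins, sex-linked genes and mitochondrial genes. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The median-of-ratios factor differed from the total-UMI factor by -0.03 (whole libraries), -0.08 (epithelial-like), -0.14 (hair cell-like), 0.03 (mesenchymal-like) and -0.01 (glial cell-like) on the log2 scale. Gene examples from lists were taken as the members with the most UMIs or the largest ratios. Genes shown by hair cell-like cluster, and the thinned genes, were chosen for their place in hair cell or regional identity, those by cluster after the clusters were seen.

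Shares of cells with a UMI were taken after each cell was thinned to 2000 UMIs, and shallower cells were left out. Further sets of clusters were defined after seeing the data: Meis2-high epithelial-like and hair cell-like clusters (at least 300 CPM), low-UMI clusters with little Malat1, and cycling clusters (Mki67 at least 100 CPM). Alternatives covered scaling, weighting of cells, cell filters, doublets, resolution, graphs, naming, class by cell, free RNA (a 5% share of each pooled profile subtracted), thinning depth and list filters. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, with random seed 1.

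The ratio step was tested on simulated counts for the whole libraries, drawn from the real means for 18810 genes with 50 genes each at 0.25, 0.5, 2 and 4-fold. The intervals held the true CPM ratio for 92, 90, 88 and 98% of these, and for 95.7% of 13811 unchanged genes. The simulated counts were Poisson draws without variation between cells. They check the code, and not the coverage for UMIs that lie in few cells. A first version compared intervals with the nominal fold instead, and held it less often, because the simulated changes moved the total by a factor of 1.02. The intervals of 8.90% of unchanged genes excluded a ratio of 1, in part through that shift. Intervals lay past 1 for 100, 96, 100 and 100% of changed genes, and 24 of 24 genes picked by the naming rule were changed ones.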

Results

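Single-cell RNA sequencing was done on adult mouse cochlear explants that carried an rtTA driver with doxycycline-inducible Myc and Notch1 intracellular domain (NICD) transgenes. Explants from mice aged 4 to 6 weeks received doxycycline (Dox, 2 µg/ml) or sterile water as vehicle for 4 days. Both groups were then infected with an adenovirus that carries Atoh1 (ad.Atoh1), the transcription factor that starts hair cell differentiation, and were cultured for 2 weeks. The comparison asks which cells and transcripts were present after ad.Atoh1 with and without prior induction of Myc and NICD. Each group was 1 library, which the labels describe as a pool with n = 5, so no difference below has a replicate check. Dox and library cannot be separated in this design. The strain labels also differ, ending in CD1 for Dox and CD2 for vehicle, and whether this marks a real difference in strain is not known. All intervals are 95% intervals for counting error only.

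The Dox library held 3005 barcodes with 35030513 UMIs, and the vehicle library held 1103 barcodes with 19470001 UMIs. After filtering, 2649 Dox cells and 1010 vehicle cells were kept. The median kept cell had 11661 UMIs and 3600 genes in the Dox library, against 16163 UMIs and 4304.5 genes in the vehicle library. Expression ratios are given as Dox over vehicle, from summed UMIs scaled to counts per 1000000 (CPM).

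Among the engineered genes, Notch1 was higher in the Dox library, while Atoh1 and Myc were lower. Notch1 (ENSMUSG00000026923) stood at 67.5 CPM in Dox and 33.5 CPM in vehicle, a ratio of 2.02 (1.85 to 2.20). Atoh1 (ENSMUSG00000073043) stood at 33.3 and 73.5 CPM, a ratio of 0.453 (0.419 to 0.490). Myc (ENSMUSG00000022346) stood at 11.9 and 15.3 CPM, a ratio of 0.778 (0.669 to 0.907). With every cell weighted alike, the Atoh1 ratio was 0.291, and the Notch1 ratio was 1.51. In GRCm38, Myc lies on the plus strand of chromosome 15 from 61985391 to 61990374, and Notch1 on the minus strand of chromosome 2 from 26457903 to 26516663. Atoh1 lies on the plus strand of chromosome 6 from 64729125 to 64731245. Reads were 3' tags, and the 3' ends of the transgenes are not given in the labels, so these counts do not check induction or infection.

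Epithelial-like and hair cell-like cells made up a larger share of the Dox library, and mesenchymal-like and glial cell-like cells a smaller one. Epithelial-like cells were 1077 of the Dox cells (40.7%, 38.8 to 42.6) and 275 of the vehicle cells (27.2%, 24.5 to 30.1), a ratio of shares of 1.49 (1.31 to 1.71). The ratio was 1.11 (0.966 to 1.28) when the marker lists were not merged. It was the same when clusters 5 and 16, whose Meis2 was high, were not counted as epithelial-like (773 Dox and 265 vehicle cells left). The cells of both clusters stayed in the totals of kept cells, and most of them were Dox cells. This value is thus lower than the ratio among the remaining cells, and does not show whether their shares differ. Mesenchymal-like cells were 86 (3.25%) and 210 (20.8%), a ratio of 0.156 (0.120 to 0.202). That ratio was 0.247 when each library was clustered alone and 0.254 when each cell took the class of its highest marker score. Glial cell-like cells were 103 (3.89%) and 117 (11.6%), a ratio of 0.336 (0.255 to 0.441). Endothelial-like cells were 14 (0.528%) and 17 (1.68%), and neuron-like cells were 3 (0.113%) and 7 (0.693%). The remaining 1229 Dox cells (46.4%) and 364 vehicle cells (36.0%) lay in 7 unnamed clusters. The median UMIs per cell in Dox and vehicle were 16661 and 21964 for the epithelial-like class, 14944 and 21092 for the hair cell-like class, 11384 and 24859 for the mesenchymal-like class and 7338 and 8377 for the glial cell-like class.

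**Figure D1:**
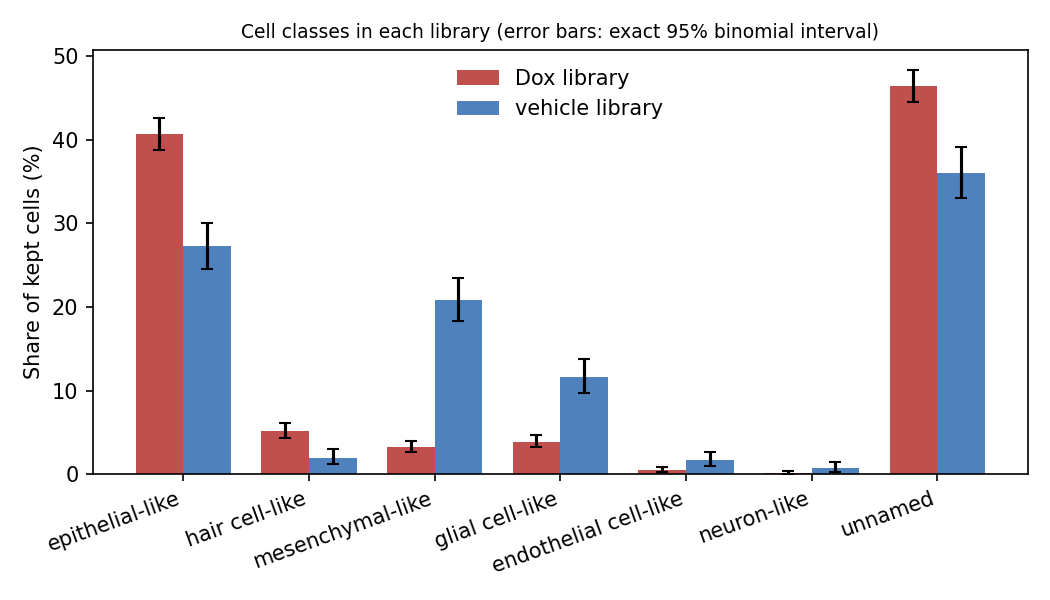
Share of kept cells (percent) in each named class for the Dox and vehicle libraries, with exact 95% binomial intervals for counting error. Epithelial-like cells were 40.7% of Dox and 27.2% of vehicle cells, and mesenchymal-like cells 3.25% and 20.8%.

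The epithelial-like class was filled by different clusters in the 2 libraries. Dox cells came mainly from clusters 3 (313 Dox and 5 vehicle cells), 5 (230 and 10), 2 (219 and 102), 10 (131 and 9), 12 (90 and 0) and 16 (74 and 0). Vehicle cells came mainly from cluster 2, cluster 13 (2 Dox and 85 vehicle cells) and cluster 15 (18 and 64). Clusters that hold cells of almost a single library may reflect that library and not a cell type. The mesenchymal-like class was led by cluster 8 in both libraries (52 and 168 cells), with cluster 19 at 28 and 16 and cluster 20 at 6 and 26. The glial cell-like class was a single cluster.

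Hair cell-like cells were 137 of the Dox cells (5.17%, 4.36 to 6.09) and 20 of the vehicle cells (1.98%, 1.21 to 3.04). The ratio of shares was 2.61 (1.63 to 4.41). They formed 2 clusters. Cluster 14, led by Ptprq, Cabp2 and Loxhd1, held 78 Dox cells (2.94%, 2.33 to 3.66) and 5 vehicle cells (0.495%, 0.161 to 1.15). Cluster 17, led by genes that include Ccer2 and Pou4f3, held 59 (2.23%, 1.70 to 2.86) and 15 (1.49%, 0.834 to 2.44), whose intervals overlap. With cluster 14 not counted as hair cell-like but its cells kept in the totals, the ratio was 1.5 (0.84 to 2.85). Both other cell filters, resolution 0.5, 2 other graphs, removal of the highest Scrublet scores and a naming rule of at least 50% of cells named only 63 to 80 Dox cells and 4 or 5 vehicle cells hair cell-like, and the ratio then lay between 5.59 and 6.67. With each library clustered alone, 128 Dox cells and 0 vehicle cells were named hair cell-like. The graph and the naming rule used here were set after the clusters were seen.

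**Figure D2:**
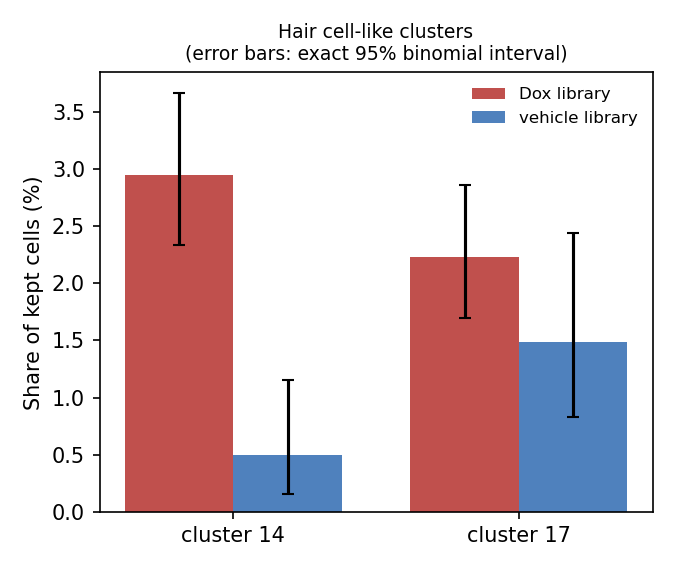
Share of kept cells (percent) in each of the 2 hair cell-like clusters for the Dox and vehicle libraries, with exact 95% binomial intervals for counting error. Cluster 14 held 2.94% of Dox and 0.495% of vehicle cells, and cluster 17 held 2.23% and 1.49%.

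Both hair cell-like clusters contained the hair cell transcription factor Pou4f3 in both libraries. In cluster 14, Pou4f3 was 239.9 CPM in Dox and 305.4 CPM in vehicle cells, and in cluster 17 it was 256.5 and 82.9 CPM. The 5 vehicle cells of cluster 14 had more Ocm, an outer hair cell calcium-binding protein gene, at 1213 CPM against 9.15 CPM in Dox cells. They also had more Otof (891 against 284 CPM), Tmc1 (776 against 303 CPM) and Gata3 (173 against 10.2 CPM). The hair cell genes Gfi1 (16.5 against 103 CPM) and Ptprq (1032 against 2250 CPM) were lower in them. Dox cells of cluster 14 had more Meis2, at 369 against 49.5 CPM, from 363 and 6 UMIs. Atoh1 was low in cluster 14, at 8.13 CPM in Dox cells (8 UMIs, in 7.69% of them) and 8.25 CPM in vehicle cells (1 UMI). In cluster 17, Ccer2 was 214 CPM in Dox and 0 in vehicle cells, Atoh1 was 105 and 46.9 CPM, and Hes6 was 563 and 800 CPM. Meis2 was 136 CPM in Dox cells of cluster 17, with a UMI in 39.0% of them, and had 0 UMIs in the 15 vehicle cells, while Gata3 was 31.0 and 93.7 CPM. Pou4f3 lies on chromosome 18 from 42394539 to 42397249 and Meis2 on chromosome 2 from 115863064 to 116065839 in GRCm38.

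After thinning each cell to 2000 UMIs, 403 Dox and 97 vehicle cells fell below that depth and were left out. Pou4f3 was then detected in 55 of 2246 Dox cells (2.45%, 1.85 to 3.18) and 3 of 913 vehicle cells (0.329%, 0.0678 to 0.957). Of thinned glial cell-like cells, 0 of 95 in Dox and 0 of 109 in vehicle had a Pou4f3 UMI, with exact upper limits of 3.81% and 3.33% for the share of cells with a UMI at this depth. Before thinning, the Pou4f3 shares were 5.32% and 1.29%. Atoh1 was detected in 3.65% of thinned Dox cells and 8.65% of thinned vehicle cells, and in 13.9% and 23.9% before thinning. In glial cell-like cells, the thinned shares were 4.21% (4 of 95 cells, 1.16 to 10.4) and 3.67% (4 of 109, 1.01 to 9.13), at unthinned median depths of 7338 and 8377 UMIs. Whether these glial UMIs came from free RNA or from infected glia is not known. Notch1 was detected in 10.7% and 8.21% of thinned cells (ratio 1.301, 0.9998 to 1.71), and in 34.7% and 31.1% before thinning. Myc was detected in 1.96% and 2.41% (ratio 0.813, 0.477 to 1.42), and in 10.1% and 17.9% before thinning. Both intervals included 1, so neither thinned share differed beyond counting error.

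Across the whole libraries, genes of Notch signalling and hair cell differentiation were higher in Dox. Of 10 measured Notch pathway targets, 9 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 1.63 (percentile 100 among 10000 expression-matched random lists). Hes5 was 15.9-fold (9.68 to 28.0) and Hey1 3.82-fold (3.38 to 4.34) higher, whereas Hes1 had a ratio of 0.685 (0.661 to 0.711). Summed over the list, CPM was 1.17-fold (1.14 to 1.21) higher. Of 5 Notch ligands, 3 were higher and 1 lower (median 0.70, percentile 98.8), with Dll3 at 5.11 and Dll4 at 0.618. Nascent hair cell genes had 17 of 23 members higher and 0 lower (median 1.24, percentile 100), with Ccer2 at 14.8 (8.98 to 26.0), Pou4f3 at 5.82 (4.51 to 7.63) and Myo6 at 1.73 (1.64 to 1.82). Of 20 measured mature hair cell genes, 13 were higher and 2 lower (median 0.89, percentile 100). The actin bundler Espn was at 6.57 (6.03 to 7.17) and Xirp2 at 7.92 (5.24 to 12.5), while Ocm was at 0.0336 (0.0151 to 0.0655). Otic progenitor genes had 9 of 19 members higher and 3 lower (median 0.53, percentile 100), with Sox2 at 1.90 and Hmga2 at 0.117. How far the larger epithelial-like and hair cell-like shares of the Dox library set these medians was not tested directly. The higher nascent hair cell list was not seen within epithelial-like (median -0.07, percentile 48.0) or hair cell-like cells (0.04, percentile 80.9). In glial cell-like cells it had a median of 0.74 (percentile 99.7) from 7 genes. Mature hair cell genes had medians of 0.36 (percentile 99.1) in epithelial-like and -0.01 (percentile 61.5) in hair cell-like cells. Notch targets, by contrast, had higher medians within epithelial-like (1.22), mesenchymal-like (2.499) and glial cell-like cells (0.85). Their median was not higher in hair cell-like cells (-0.33) or in epithelial-like cluster 2 alone (-0.10).

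Genes of the matrix, of interferon signalling and of antigen presentation were lower in Dox. All 20 extracellular matrix genes were at least 1.5-fold lower (median -2.63, percentile 0), with Vim at 0.176 (0.171 to 0.180) and Sparc at 0.179 (0.176 to 0.183). Interferon response genes had 14 of 18 members lower and 0 higher (median -1.23, percentile 0), with Isg15 at 0.352 and Bst2 at 0.439. MHC class I genes had 8 of 10 members lower (median -0.81, percentile 0.12), with B2m at 0.376. Of 15 measured inflammatory genes, 12 were lower and 2 higher (median -2.17, percentile 0). Summed over that list, however, CPM was 3.60-fold higher in Dox, because Lcn2, an iron-sequestering defence protein gene, was 5.16-fold (5.11 to 5.21) higher. Within epithelial-like, hair cell-like, mesenchymal-like and glial cell-like cells, the inflammatory medians were 0.94, 0.80 (3 genes), -0.10 and -0.01. The matrix medians were -1.49, -0.14, -0.64 and -0.20. How far the smaller mesenchymal-like share of the Dox library (3.25% against 20.8%) set the whole-library medians was not tested.

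G2 and M phase genes were lower in the whole Dox library, with 0 of 17 members higher and 6 lower (median -0.52, percentile 0.14). S phase genes had 0 of 18 higher and 6 lower (median -0.29, percentile 3.29), inside the central 95% of random lists. With every cell weighted alike, the G2 and M phase median was -0.06, at percentile 68.7. Of 26 Myc targets and ribosome biogenesis genes, 1 was higher and 1 lower (median 0.21, percentile 98.7), and Npm1 was at 1.57 (1.54 to 1.60). With every cell weighted alike, the median of that list was 0.03, at percentile 91.5. Cell cycle inhibitor and senescence genes had 2 of 11 members higher and 2 lower (median 0.09, percentile 76.5), also inside that range. Immediate early genes, which tissue dissociation induces, had 7 of 15 members higher and 0 lower (median 0.58, percentile 100), with Jun at 2.11 and Egr1 at 1.90. Glycolysis and hypoxia genes had 6 of 16 higher and 1 lower (median 0.47, percentile 100), with Pgk1 at 1.65 (1.61 to 1.69).

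The remaining lists also lay inside the central 95% of random lists. Supporting cell function genes had 5 of 15 members higher and 4 lower (median 0.21, percentile 94.1), with Otog at 3.33 and Epyc at 0.549. Wnt targets had 4 of 14 higher and 4 lower (median -0.29, percentile 8.77). The p53 and integrated stress response list had 2 of 14 higher and 3 lower (median -0.28, percentile 2.62), with Chac1 at 0.512. Cholesterol and lipid synthesis genes had 1 of 14 higher and 3 lower (median -0.11, percentile 20.3). Metallothionein and oxidative stress genes had 1 of 11 higher and 4 lower (median -0.07, percentile 39.2). Of 3 engineered genes, 1 was higher and 1 lower (median -0.36, percentile 12.2). As technical lists, 2 of 5 sex-linked genes were higher (median 0.51, percentile 96.0), with Xist at 1.64, and 1 of 13 mitochondrially encoded genes was higher (median 0.20, percentile 95.03).

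**Figure D3:**
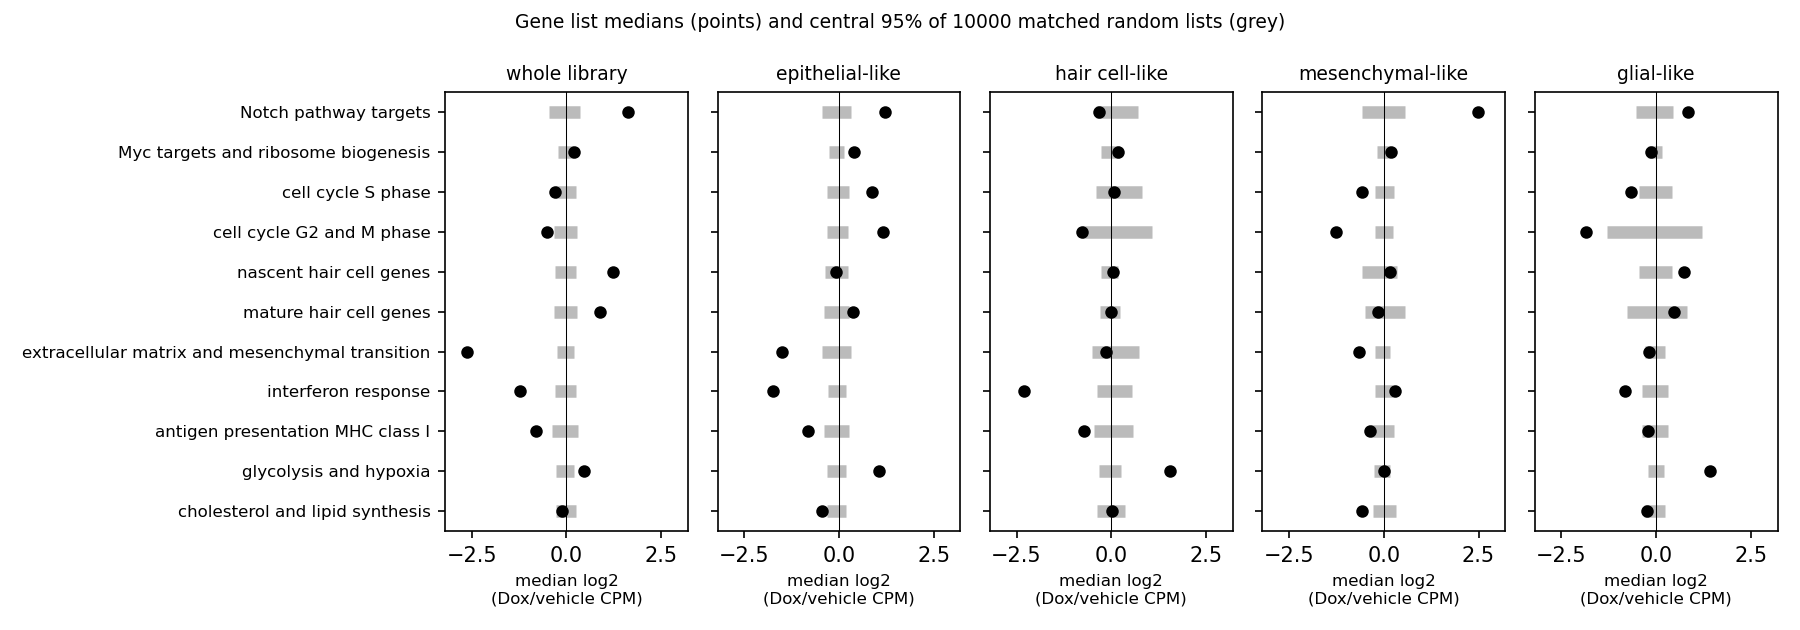
Median log2 ratio (Dox over vehicle) of each gene list in the whole libraries and in each class that was compared. Notch pathway targets had a median of 1.63 and extracellular matrix genes of -2.63 in the whole libraries.

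By the size rule, the whole-library genes highest in Dox were Gabrp (147-fold, 50.2 to 715), Car9 (27.4), Olfm4 (23.8), Otol1 (22.1), Ehf (17.2), Alox12e (17.1), Agr3 (15.9), Cited1 (15.3), Nrxn3 (15.3), S100a14 (14.1), Kcnh7 (12.2) and Chil1 (11.3). Car9 encodes a hypoxia-responsive carbonic anhydrase, and Otol1 an otoconial matrix protein of the vestibular organs. The genes lowest in Dox were Has2 (0.0218), the collagen genes Col1a2 (0.028, 0.0264 to 0.0296), Col1a1 (0.0288) and Col2a1 (0.0364), Ceacam16 (0.0299), Ibsp (0.0309), Ptx3 (0.0345), Thbs2 (0.038), Plaur (0.0478), Mmp13 (0.0498), Cdh11 (0.0501) and Cxcl12 (0.0557). Ibsp encodes a bone matrix protein, and Ceacam16 a tectorial membrane protein. Otol1, Gabrp, Olfm4 and Chil1 led clusters made almost only of Dox cells, and Ceacam16 led a cluster with 85 vehicle and 2 Dox cells.

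Marker lists of cell types followed the class shares. Hair cell markers had 20 of 27 measured members higher and 2 lower (median 1.35, percentile 100). Other cochlear epithelial markers had 11 of 22 higher and 5 lower (median 0.60, percentile 100), and stria marginal cell markers 4 of 8 higher and 1 lower (median 0.66, percentile 99.9). Supporting cell markers were mixed, with 7 of 18 higher and 7 lower (median -0.21, percentile 8.8). Middle ear and keratinocyte markers had 5 of 6 higher and 1 lower (median 2.13, percentile 100), with Foxj1 at 7.18 and Bpifa1 at 9.30, although the labels say that the middle ear was removed. Skeletal muscle markers had 3 of 6 higher and 1 lower (median 0.78, percentile 96.0).

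Markers of most non-epithelial cells were lower in Dox. All 15 fibroblast markers (median -3.04, percentile 0), all 12 osteoblast and chondrocyte markers (median -2.58, percentile 0) and all 13 macrophage markers (median -5.45, percentile 0) were at least 1.5-fold lower. Lyz2, for instance, had 18 UMIs in Dox and 3243 in vehicle (ratio 0.00307), the latter in 2.18% of vehicle cells. Lower in Dox were also 4 of 5 spiral ligament (median -0.96, percentile 2.18), 6 of 9 endothelial (median -1.27, percentile 0.11), 9 of 14 glial (median -1.33, percentile 0) and 9 of 11 neuron markers (median -1.60, percentile 0). Among blood and pigment cells, 4 of 5 lymphocyte (median -2.23, percentile 0.365) and 4 of 6 melanocyte markers (median -1.39, percentile 0.68) were lower. Of osteoclast markers, 4 of 5 were lower (median -2.499, percentile 0.185), and of pericyte markers 5 of 9 were lower and 2 higher (median -0.61, percentile 2.42). Neutrophil markers had 1 of 4 higher and 1 lower (median -0.34, percentile 29.5). Only 1 erythroid marker was measured.

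Within the epithelial-like class, genes of proliferation and glycolysis and 6 of 10 Notch targets were higher in Dox cells. The interferon, MHC class I and matrix lists were lower by their medians. G2 and M phase genes had 15 of 17 members higher (median 1.16, percentile 100), with Ube2c at 2.19 (1.89 to 2.54) and Mki67 at 2.01 (1.61 to 2.53). S phase genes had 12 of 18 higher and 0 lower (median 0.88, percentile 100), and Myc targets 7 of 26 higher and 0 lower (median 0.39, percentile 100), with Npm1 at 2.19. Glycolysis genes had 13 of 16 higher (median 1.06, percentile 100), with Ldha at 4.42 (4.17 to 4.69). Notch targets had 6 of 10 higher and 1 lower (median 1.22, percentile 100), with Notch3 at 4.43 (3.17 to 6.37) and Hes1 at 0.548 (0.520 to 0.577). Summed CPM of the Notch list was lower in Dox, however, at 431.6 against 471 CPM (ratio 0.916, 0.878 to 0.955). Inflammatory genes had 7 of 11 higher (median 0.94, percentile 100). Interferon genes had 16 of 18 lower and 0 higher (median -1.74, percentile 0), with Ifit3 at 0.147 (0.125 to 0.173). MHC class I genes had 5 of 10 lower (median -0.82, percentile 0), and matrix genes 12 of 18 lower and 4 higher (median -1.49, percentile 0). Fibroblast markers were lower in the same cells, with 6 of 10 lower and 1 higher (median -1.05, percentile 0.07), as were other cochlear epithelial markers, with 10 of 22 lower and 8 higher (median -0.37, percentile 0.46), while stria marginal cell markers had 4 of 8 higher and 2 lower (median 0.545, percentile 99.7). Immediate early genes, which dissociation induces, had 7 of 15 higher and 1 lower (median 0.497, percentile 100), and cholesterol and lipid synthesis genes 6 of 14 lower and 1 higher (median -0.43, percentile 0.27). Nascent hair cell genes had 3 of 23 higher and 8 lower (median -0.07, percentile 48.0), inside the random range. Mature hair cell genes had 6 of 13 higher and 3 lower (median 0.36, percentile 99.1). Notch1 was at 1.60, Myc at 1.13 and Atoh1 at 0.353. With both libraries pooled, cluster 2 (219 Dox and 102 vehicle cells) had the most Atoh1 and the least Notch1 of the epithelial-like clusters, at 95.6 and 30.6 CPM. Cluster 13 came next in both, at 10.99 and 49.05 CPM. The Atoh1 and Notch1 ratios may thus reflect the mix of clusters, which was not tested.

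Cluster 2, which held 219 Dox and 102 vehicle cells, was also compared alone. There, glycolysis genes had a median of 0.76 (percentile 100), interferon genes of -1.39 (percentile 0) and MHC class I genes of -0.85 (percentile 0.01), while matrix genes had a median of -0.47 (percentile 2.22). The medians were -0.26 for G2 and M phase genes, -0.10 for Notch targets and 0.08 for S phase genes, all inside the random range. The higher cell cycle and Notch values of the class were thus not seen in this cluster. Thinned to 2000 UMIs, Mki67 was detected in 3.36% of Dox and 1.504% of vehicle epithelial-like cells, and in 10.0% and 4.36% before thinning.

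Among single genes of the epithelial-like class, those highest in Dox were the lectin gene Reg3g (97.2-fold, 47.1 to 242), Mybpc1 (116), Gabrp (108), Ndufa4l2 (102), Sbspon (69.4), Cp (53.1), Otol1 (38.8), Hpse2 (38.1), Car9 (30.7) and Sparcl1 (18.2). Cdca7 (196 UMIs against 0) and Tnfsf11 (146 against 0) were higher by at least 4.38 and 3.95 on the log2 scale. The lowest were Ceacam16 (0.0141, 0.0112 to 0.0176), Pilrb1 (0.0149), Apoc3 (0.0188), Hamp2 (0.0275), Hmx1 (0.0303), Ly6a (0.0347), Hamp (0.0397), Hsd17b6 (0.0449), Tdrd12 (0.0492), Ifit3b (0.0684), Crisp1 (0.0684) and Lgals1 (0.0779). Reg3g, Gabrp, Otol1, Hpse2, Ceacam16, Ly6a, Hamp and Hamp2 were leading genes of clusters held mostly by 1 library. In cluster 2 alone, UMIs in Dox and vehicle were 4 and 0 for Cdca7, 2 and 0 for Tnfsf11, 3 and 2 for Hpse2 and 0 and 2 for Hsd17b6, too few to show a direction.

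Hair cell-like cells from Dox had more glycolytic and less interferon transcript, from 137 Dox and 20 vehicle cells. Cluster 14 held most of the Dox cells and cluster 17 most of the vehicle cells. The median of all genes was shifted by -0.14 on the log2 scale in this class. Hair cell markers had 11 of 27 higher and 7 lower (median 0.22, percentile 98.7), and supporting cell markers 7 of 13 lower and 4 higher (median -0.73, percentile 0.025). Neuron markers had 4 of 9 higher and 1 lower (median 0.49, percentile 89.96), with a summed CPM 3.35-fold (2.65 to 4.29) higher, and middle ear and keratinocyte markers summed to 242 and 6 UMIs (ratio 7.07, 3.202 to 19.5). Glycolysis genes had 15 of 16 members higher (median 1.55, percentile 100), with Ldha at 6.18 (4.19 to 9.52) and Gapdh at 2.67 (2.41 to 2.97). All 13 measured interferon genes were lower (median -2.29, percentile 0), with Oasl2 at 0.114 (0.0668 to 0.191), and 6 of 8 MHC class I genes were lower (median -0.72, percentile 0.26). In cluster 17 alone the medians were 0.78 for glycolysis and -2.54 for interferon genes. Nascent hair cell genes had 6 of 23 higher and 4 lower (median 0.04), and mature hair cell genes 8 of 20 higher and 7 lower (median -0.01, with Strc at its bound). In cluster 17 alone the mature list had a median of 0.79, at percentile 100. Metallothionein genes had 3 of 9 higher and 0 lower (median 0.54, percentile 99.1).

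The genes highest in Dox hair cell-like cells were Spp1 (359-fold, 99.2 to 2963, from 4093 and 2 UMIs), Lcn2 (84.6), Lpgat1 (75.4), Fam183b (62.1), Atp2b2 (61.7), Cib3 (57.4), Plxna4 (36.1), Kcnh7 (22.3) and Nrxn3 (14.5). Car12, Pcdh20 and Pifo had 549, 348 and 268 UMIs against 0, at least 5.00, 4.35 and 3.97 higher on the log2 scale. The lowest were Ocm (0.0107, 9 and 147 UMIs), Apoc3 (0.011), Nwd1 (0.0139), Garnl3 (0.0198), Dnah10 (0.0296), Atpaf2 (0.0528), Lmod3 (0.0529), Lifr (0.056), Rorb (0.0584), Dgkb (0.0592), Hes1 (0.0877) and Srpk1 (0.0907). Ocm, Nwd1, Dnah10 and Lifr had UMIs in only 15% of the 20 vehicle cells, so these ratios rest on 3 cells each. Without cluster 14, Car12, Fam183b, Atp2b2 and Pcdh20 had 6, 6, 5 and 12 UMIs in Dox and 0 in vehicle cells, and Spp1 had 0 and 2 (upper interval bound of the ratio 1.15), so no direction could be read at this depth. Nor could one for Lcn2 after a 5% share of each library's pooled profile was subtracted, which left it under 3 counts in both libraries, or for Lifr when cells took the class of their highest marker score (26 and 0 UMIs, lower interval bound of the ratio 0.827).

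Mesenchymal-like cells went the other way from epithelial-like cells in the cell cycle lists. All 17 G2 and M phase genes were lower in Dox (median -1.26, percentile 0), with Top2a at 0.412 (0.326 to 0.515) and Mki67 at 0.528 (0.358 to 0.756). S phase genes had 8 of 18 lower and 0 higher (median -0.58, percentile 0). Thinned to 2000 UMIs, Top2a was detected in 3.57% of Dox and 11.1% of vehicle mesenchymal-like cells, against 10.5% and 21.4% before thinning. Notch targets had 5 of 7 members higher and 1 lower (median 2.499, percentile 100), with Hey1 at 12.7 (6.47 to 26.9), but the summed CPM of the list was only 1.18-fold (1.06 to 1.32) higher. Matrix genes had 11 of 20 lower and 0 higher (median -0.64, percentile 0). Interferon genes had 7 of 17 higher and 3 lower (median 0.29, percentile 99.2), and supporting cell function genes 8 of 9 higher (median 1.67, percentile 100), with Epyc at 56.9 (26.6 to 146). In the same cells, other cochlear epithelial markers had 11 of 12 higher and 1 lower (median 4.18, percentile 100), and their summed CPM was 12.8-fold (10.6 to 15.4) higher. Fibroblast markers had 7 of 15 lower and 1 higher (median -0.49, percentile 0.03), and osteoblast and chondrocyte markers 7 of 11 lower and 3 higher (median -1.40, percentile 0). Pericyte (median 0.79, percentile 99.98), endothelial (median 0.796, percentile 99.8) and glial markers (median 0.53, percentile 99.6) were higher by their medians, although the summed CPM of the glial markers had a ratio of 0.9696 (0.862 to 1.09). Spiral ligament markers had 2 of 4 higher and 1 lower (median 1.28, percentile 99.8), and supporting cell markers 5 of 10 higher and 3 lower (median 0.44, percentile 98.8). MHC class I genes had 1 of 10 higher and 1 lower (median -0.36, percentile 2.03). Immediate early genes had 7 of 15 higher and 0 lower (median 0.52, percentile 100), mitochondrially encoded genes 2 of 13 higher and 0 lower (median 0.315, percentile 99.8) and glycolysis genes 1 of 16 higher and 2 lower (median 0.0047, percentile 64.6). The interferon median was -0.10 when cells took the class of their highest marker score. Wnt targets had 8 of 14 higher (median 0.76, percentile 100).

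By the size rule, Krt18 (148-fold, 70 and 2 UMIs) and Krt8 (84.8, 60 and 3 UMIs), which are keratin genes of simple epithelium, were highest in Dox mesenchymal-like cells. They were followed by Mmp9 (23.9), Kcnj8 (19.8), Gpx2 (15.7), Atp1b1 (13.3), Igfbp3 (9.64), Cxcl13 (8.97), Mybpc1 (8.20), Cxcl10 (7.93), Otor (7.10) and Gal (5.45). Lowest were Sct (0.037), Col8a2 (0.0428, 0.00107 to 0.244), Comp (0.0958), Col2a1 (0.123), Has2 (0.133), Rspo3 (0.155), Col1a2 (0.159), Ptx3 (0.17), Fgf7 (0.17), Col1a1 (0.177) and Tnc (0.186). Serpinb6b had 0 UMIs in Dox and 69 in vehicle cells, a log2 ratio of at most -2.44. After 5% of each pooled profile was subtracted, Krt18 and Gpx2 had under 3 counts in both libraries. Otor, Cxcl13 and Cxcl10 were leading genes of cluster 19 (28 Dox and 16 vehicle cells), and Col1a2, Col1a1 and Ptx3 of cluster 8 (52 and 168). Cxcl10 is also a member of the interferon list. How far this mix of clusters set the ratios and list medians of the class was not tested.

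Glial cell-like cells from Dox had more glycolytic and Notch target transcript and less of the glial markers. Of 14 glial markers, 0 were higher and 11 lower (median -0.85, percentile 0), and their summed CPM had a ratio of 0.459 (0.444 to 0.475). Melanocyte markers had 3 of 4 lower (median -2.57, percentile 0) and supporting cell markers 6 of 11 lower and 2 higher (median -0.80, percentile 0.04). The melanocyte markers Dct (0 and 102 UMIs) and Mlana (1 and 16 UMIs) were each found in only 0.855% of vehicle cells. That median thus rests largely on very few cells. Fibroblast markers had 2 of 7 higher and 3 lower (median -0.046, percentile 46.7), and their summed CPM had a ratio of 0.722 (0.653 to 0.797). Stria marginal cell markers had 2 of 4 higher and 0 lower (median 0.57, percentile 98.7). Glycolysis genes had 14 of 15 members higher (median 1.43, percentile 100), with Pgk1 at 2.70 (2.33 to 3.13). Notch targets had 4 of 6 higher and 0 lower (median 0.85, percentile 99.9). Interferon genes had 8 of 14 lower and 1 higher (median -0.82, percentile 0), but their median was 0.05 with every cell weighted alike. S phase genes had 7 of 13 lower and 2 higher (median -0.67, percentile 0.16), and all 4 measured G2 and M phase genes were lower (median -1.86). Nascent hair cell genes had 4 of 7 higher (median 0.74, percentile 99.7). Highest were Ucma (33.5), Igfbp2 (18.1), Rarres1 (12.3), Ltc4s (9.62), Cox7a1 (9.54), Btbd17 (8.95), Slc16a3 (8.41), Thrsp (8.37), Mgp (7.16), Ncbp3 (5.80), Cck (4.72) and Tnnt2 (4.71). Lowest were Pzp (0.0674), Cxcl14 (0.0682), Ceacam10 (0.111), Ngfr (0.121), Lrrtm4 (0.121), Met (0.13), Lsamp (0.13), Ccl8 (0.147), Tmem158 (0.149), Hmga2 (0.151) and Nav3 (0.229).

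Epithelial-like and hair cell-like cells were also split by the presence of an Atoh1 UMI within each library. In Dox, 201 cells had an Atoh1 UMI and 1013 did not, and nascent hair cell genes summed to 4923 and 1385 CPM, a ratio of 3.55 (3.49 to 3.62), which was 2.21 (2.18 to 2.24) over all kept cells. In vehicle, 84 cells had one and 211 did not, at 3198 and 1701 CPM, a ratio of 1.88 (1.82 to 1.94). Mature hair cell genes had ratios of 1.49 (1.44 to 1.54) in Dox and 0.765 (0.712 to 0.822) in vehicle, but the latter was 1.39 (0.857 to 2.15) after thinning. Pou4f3 was detected in 18.4% of Dox cells with an Atoh1 UMI and 7.21% of those without. In vehicle the shares were 4.76% (1.31 to 11.8) and 3.79% (1.65 to 7.33). Hes6, a gene of early hair cells, had CPM ratios of 4.29 and 3.50. Ccer2 was at 14.8 (11.6 to 18.9) in Dox, with a UMI in 9.95% of cells with Atoh1. In vehicle it was at 0.682 (0.153 to 2.44), from 4 and 9 UMIs, which show no direction. Gfi1 was at 1.05 (0.688 to 1.57) in Dox and 2.15 (0.887 to 5.40) in vehicle. Cells with an Atoh1 UMI were deeper, at median UMIs of 21200 against 15290 in Dox and 30516.5 against 17684 in vehicle. Before thinning, 19.4% of Dox and 8.55% of vehicle glial cell-like cells had an Atoh1 UMI.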

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

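Of the tests here, the one on vestibular hair cells in cluster 14 was chosen after its result was seen, and so were the cluster sets and the spread rule for the cycling epithelial cluster. Median log2 ratios (Dox over vehicle) of 3 gene lists had opposite signs in epithelial-like and mesenchymal-like cells, and these differences between classes were not tested. S phase genes had a median log2 ratio of 0.88 in epithelial-like and -0.58 in mesenchymal-like cells. G2 and M phase genes had 1.16 and -1.26, and interferon response genes -1.74 and 0.29, the latter at -0.10 when cells took the class of their highest marker score.

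The first pattern is the opposite sign of the cell cycle lists. Without the cycling mesenchymal cluster the mesenchymal G2 and M phase median was -1.58 (-2.73 to -0.68), and without the Meis2-high clusters the epithelial one was 1.54 (1.05 to 1.70), so neither set of clusters alone carries its side. Without the cycling epithelial cluster (131 Dox and 9 vehicle cells) the epithelial median was 0.61 (0.34 to 1.22), just above the bound of log2 1.5 set beforehand, and the rule that its spread must clear that bound was added after a first reading had excluded this explanation. That cluster may therefore carry much of the epithelial side. The other mesenchymal-like clusters also differed in mix, with 52 Dox and 168 vehicle cells in cluster 8 and 28 and 16 in cluster 19. Their Mki67 was 9.37 and 2.05 CPM, and how far this mix set the mesenchymal side was not tested. A biological effect of Myc and NICD stays open and untested, since Dox and library are the same split.

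The second pattern is that epithelial-like and hair cell-like clusters with high Meis2 (5, 14 and 16) held 382 Dox cells (14.4%) and 15 vehicle cells (1.49%). Against the other Dox cells of these classes, 3 of 3 genes of non-sensory vestibular tissue were at least 2-fold (Otop1 2.97, Hmx3 9.94, Dlx5 20.2, from clusters 5 and 16). This outcome had been predicted for carried-over vestibular tissue, although the labels say that the vestibular region was removed. Of 3 cochlear genes, 2 were at most 0.5-fold (Fst 0.0421 and Fgfr3 0.474), with Hey2 at 1.21. Fgfr3 rests on 9 and 46 UMIs (upper interval bound 0.980). By the prediction this counted against kept cochlear identity. The sets compared may hold different cell types, however, so the cochlear genes cannot decide this. Meis2 in vehicle cells of these clusters was 13.5-fold (8.57 to 21.1) of other vehicle cells, mostly from 10 cells of cluster 5, but these clusters were chosen for their Meis2 level, so this value excludes nothing and a change that Dox brought about in cochlear cells stays open. For cluster 14, 0 of the 3 vestibular genes were at least 2-fold, but these are not hair cell genes, so vestibular and cochlear hair cells cannot be told apart by this test. Dox cells of cluster 14 had Meis2 at 7.45-fold, Gata3 at 0.0587 and Nr2f1 at 0.114 of its 5 vehicle cells. In the Meis2-high Dox cells as a set, Gata3 was at 0.160 and Nr2f1 at 0.0336 of the other Dox cells. Cluster 14 may thus hold different hair cells in the 2 libraries, and whether its Dox cells are vestibular stays open. If vestibular cells are present, the larger epithelial-like and hair cell-like shares of Dox may come partly from them. With these clusters not counted in their classes, the ratios of shares were 1.11 (0.966 to 1.28) and 1.5 (0.84 to 2.85). Their cells stayed in the totals of kept cells, which lowers these ratios. Cluster 17, which was still counted, also held Meis2 in 39.0% of its 59 Dox cells and in 0 of its 15 vehicle cells.

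The third pattern is that clusters 1, 4 and 6, with few UMIs and little Malat1, held 729 Dox cells (27.5%) and 141 vehicle cells (13.96%), at median UMIs of 2349 and 2602. In the Dox library, 3 of 3 other nuclear RNAs were at most 0.5-fold of named epithelial-like cells (Neat1 0.1004, Meg3 0.0263, Kcnq1ot1 0.0412), and Malat1 was at 0.0215 in Dox and 0.118 in vehicle. Cell fragments without nuclei are a candidate explanation. Without these clusters, 0% of the whole-library lists outside the random range moved into it or changed sign. Those medians come from summed UMIs, to which such shallow cells add little, so this outcome was largely set by their depth. It says nothing about medians with every cell weighted alike, which were not tested without these clusters. Whether Dox or the handling of the explants led to more such barcodes was not tested.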

How the results depend on the processing

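No paired analysis was possible because each group is 1 library and the labels share no replicate numbers. The alternatives for graphs, naming, Scrublet scores, cluster sets and the cells used for the Atoh1 split were chosen after seeing the data; the rest were set before. Direction was kept in every alternative that gave a value for the glial cell-like share (0.305 to 0.381), the Myc ratio (0.6995 to 0.7999) and the thinned shares of Pou4f3 (5.34 to 7.40) and Atoh1 (0.478 to 0.542). The thinned ratios of Notch1 and Myc, whose intervals included 1, lay at 1.37 to 1.47 and 0.703 to 0.854. All 24 named genes stayed at least 1.5-fold in the reported direction in every alternative run for the whole libraries and glial cell-like cells, as did 22 to 24 in mesenchymal-like, 19 to 24 in epithelial-like and 18 to 24 in hair cell-like cells, where genes without a readable direction count as not kept. Lists outside the random range numbered 11 to 13 (whole), 9 to 12 (epithelial-like) and 9 to 13 (mesenchymal-like). Where values moved, the cause was not tested. Hair cell-like values rest on 20 vehicle cells.

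The ratio of hair cell-like shares (2.61) was 5.87 with at least 200 genes and up to 30% mitochondrial UMIs, and 6.67 with at least 1000 genes and up to 10%. It was 5.95 at resolution 0.5 and 5.95 when at least 50% of cells had to have the class as own best. It was 5.87 with the UMAP graph, 6.29 with 15 neighbours and 5.59 without the highest Scrublet scores. With the Meis2-high clusters not counted but kept in the totals, it was 1.5. Clustered alone, the vehicle library gave no hair cell-like cells, so there is no ratio. The epithelial-like ratio (1.49) was 1.79 with each library clustered alone and 1.76 with each cell's highest marker score. It was 1.11 with the Meis2-high clusters likewise not counted, and 1.11 with unmerged marker lists, where no cluster was named mesenchymal-like. The mesenchymal-like ratio (0.156) was 0.247 with libraries clustered alone and 0.254 with highest marker scores. The unnamed ratio was 0.882 (reversed) with libraries clustered alone.

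With every cell weighted alike, the ratios were 1.51 for Notch1 and 0.291 for Atoh1, and the glial cell-like medians were 0.091 for supporting cell function and 0.0499 for interferon genes (both reversed), with 5 and not 9 lists outside the random range. With each cell's highest marker score, reversed values were 0.074 (supporting cell function) and -0.090 (metallothioneins) in glial cell-like cells, and -0.10 for mesenchymal-like interferon genes. Lifr in hair cell-like cells then had 26 and 0 UMIs, which show no direction (lower interval bound of the ratio 0.827). With members of at least 1 UMI, the reversed medians were -0.066 for mature hair cell genes in epithelial-like cells and -0.093 for metallothioneins in glial cell-like cells, both with members at the 3-count floor. In hair cell-like cells, 3 and not 5 lists lay outside the random range with highest marker scores, 3 with members of at least 50 UMIs and 3 without the Meis2-high clusters. Of the 5, the G2 and M phase median was set by a gene with 0 vehicle UMIs and gives no direction. After 5% of the pooled profile was subtracted, Lcn2 in hair cell-like cells and Krt18 and Gpx2 in mesenchymal-like cells were under 3 counts in both libraries, so they have no value. In cluster 2 alone, reversed medians were -0.10 (Notch targets) and -0.26 (G2 and M phase genes), and Cdca7, Tnfsf11, Hpse2 and Hsd17b6 had 4, 2, 3 and 0 Dox and 0, 0, 2 and 2 vehicle UMIs, which show no direction. Without the Meis2-high clusters, Spp1 in hair cell-like cells had 0 and 2 UMIs, and Car12, Pcdh20, Fam183b and Atp2b2 had 6, 12, 6 and 5 Dox and 0 vehicle UMIs, which show no direction.

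For cells with an Atoh1 UMI, the nascent list ratio in Dox (3.55) was 3.95 with at least 2 Atoh1 UMIs, 2.83 thinned and 2.21 over all kept cells, and the mature one (1.49) was 1.58, 1.57 and 1.35. In vehicle the nascent ratio (1.88) was 1.79, 1.51 and 1.70, and the mature one (0.765) was 0.681, 1.39 (reversed) and 0.964.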

Other observations

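Among the 23 clusters, with the cells of both libraries pooled, Atoh1 transcript was highest in 2 that stayed unnamed. Atoh1 stood at 644.5 CPM in cluster 9, which held 74 Dox cells (2.79%) and 87 vehicle cells (8.61%), and at 179.9 CPM in cluster 11, which held 44 (1.66%) and 86 (8.51%). The next levels were 95.6 CPM in epithelial-like cluster 2 and 95.04 CPM in hair cell-like cluster 17. Hes6 was 30.3 CPM in cluster 9, 579 CPM in cluster 11, 467.5 CPM in cluster 2 and 605 CPM in cluster 17, and Pou4f3 was 0, 0.324, 3.61 and 226 CPM. Cluster 9 cells were shallow, with a median of 4760 UMIs, and were led by unnamed gene models and Mgat4b. Cluster 11 cells had a median of 18739 UMIs and were led by Mfap4, Tnnt1 and C1ql1. Macrophage markers scored highest in cluster 11, with 9 detected, but only 7.70% of its cells had that class as their own best. The clusters with the most pooled Atoh1 transcript were thus not those with the most Pou4f3.

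Cluster 0, unnamed because its top genes also held a hair cell marker, was 337 Dox cells (12.7%) and 49 vehicle cells (4.85%). It was led by Neurod1, a neurogenic transcription factor gene, with Anxa4 and Cib2, genes of the hair cell lists, also among its top genes. Hes6 was 668 CPM and Epcam 754 CPM in this cluster, while Pou4f3 was 7.89 CPM and Atoh1 21.04 CPM. The values of these clusters describe 1 library per group, and no explanation was tested.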
